A study of Bos taurus with 12 samples.

How the data were processed

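Gene expression was measured with 1-colour Agilent arrays in the corpus luteum, the progesterone-secreting gland of the ovary, of Japanese Black cows. Per the labels, 4 cows were sampled on day 15 of the estrous cycle (NP15), 4 on day 15 of gestation (P15) and 4 on day 18 of gestation (P18), with the day of insemination counted as day 1. The tissue was taken 10 to 30 min after exsanguination. Total RNA was prepared with a column kit, and 400 ng was amplified and labelled with Cy3, per the labels' protocols. Each array had 15208 probes other than controls and 536 control spots, laid out in 192 rows and 82 columns.

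The scanner files hold spot intensities on a linear scale, made by the authors with Agilent Feature Extraction, version 9.5 per the submitters' processing notes and 9.5.1.1 per the file headers. The processed signal in these files is corrected for background and for a spatial trend by that software, per the file headers. The deposited value table holds log2 values; set against the scanner values, each of its columns was log2 of the processed signal minus a constant of that array. That constant differed from the array's 75th percentile by -0.0076 to -0.0142 log2 units, and no value strayed from it by more than 1.79e-06. Its scale and direction are therefore known, and the column medians lay between -3.32 and -2.99. What the authors did after these files is not given in the sources used here.

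Values were taken as log2 of the processed signal minus the array's 75th percentile over the probes. Control spots were left out, and spots marked as non-uniform or as population outliers were set to missing, at most 9 probes per array. A probe was kept when it was well above background on at least 3 of the 4 arrays of a group, which left 12605 probes, 9837 of them well above background on all 12 arrays. Where a gene had several kept probes the brightest one stood for it, which left 12321 genes. Of these, 182 genes had 2 or more kept probes.

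Gene names came from the probes' accession, gene number, symbol or description, looked up in a table of bovine genes of the assembly ARS-UCD2.0, used for names only. By accession 2514 probes were matched, by gene number 2017, by symbol 1295, by an older symbol 292 and by description 998, and 8092 were not matched. In all, 7060 probes had a gene symbol, for 6724 different symbols, and 56 were matched only to a locus number. Of the genes tested, 5919 had a symbol.

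Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on group means of all 12 arrays, which share the estimate of the spread). P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A fold is reported as "at least" a value where a probe was not well above background on any array of a group. Its bound sets the brighter group's mean against, on each dim array, the higher of the probe's own signal and the lowest signal well above background. No fold is given where that bound was under 1.

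The genes in the text were chosen by a rule: PPARD and CYP21A2, which the title of the series names; the 8 largest rises and the 8 largest falls among called genes with a symbol whose groups did not overlap; and up to 4 members with the smallest p from each gene list. Members are named for the lists described in detail, and counts are given for the others. A gene with several of these roles is named once, and probes not well above background in both groups get no value. Of the genes picked by this rule, 1 is not reported here.

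There were 26 lists, 17 of pathways and 9 of cell types. The pathway lists were interferon-stimulated genes, steroid and progesterone synthesis, cholesterol synthesis and uptake, PPAR and retinoid receptors with lipid oxidation targets, prostaglandin synthesis and receptors, chemokines and cytokines, angiogenesis and vascular tone, lymphatic vessels, extracellular matrix and proteases, apoptosis and luteal regression, oxidative phosphorylation, cytosolic ribosomal proteins, immediate early and heat shock genes, hypoxia and glycolysis, cell cycle, complement and coagulation, and antigen presentation. The cell type lists covered luteal steroidogenic cells, endothelial cells, fibroblasts with pericytes and smooth muscle, macrophages and other myeloid cells, T cells and natural killer cells, B and plasma cells, red blood cells and platelets, follicle and ovarian stroma, and trophoblast. Lists were tested with limma's camera at a preset correlation of 0.01 over 12302 genes without missing values, adjusted over the 25 lists with at least 3 members. The estimated-correlation form of camera and limma's fry were run beside it. Lists overlap in part, such as the collagens in the matrix and fibroblast lists.

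The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the deposited values, no filter, only probes well above background on all 12 arrays, the mean of a gene's probes, marked spots kept, eBayes with trend and robust, array weights, the 8 arrays of the 2 groups alone, slide as a fixed block, a replicate block, a threshold of 1.5-fold beside the adjusted p, and each array left out in turn. Alternatives chosen after seeing the data were leaving out the first and the last 24 rows of the array, a local position adjustment (each spot against its neighbours within 2 rows and 4 columns), cyclic loess, and the other probe of PPARD. Because P18 lay alone on its slide, the slide block could be fitted only for P15 vs NP15.

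The procedure was tested on simulated data of 12302 genes with 200 changed. For P15 vs NP15, 19.4% of the genes changed 1.5-fold, 59.7% of those changed 2-fold and 87.9% of those changed 4-fold were recovered, with 3 false calls. For P18 vs NP15 these shares were 16.4%, 58.2% and 80.3%, with 4 false calls, and for P18 vs P15 19.4%, 58.2% and 78.8%, with 2. On unchanged arrays 0 of the 25 lists was called by camera in each comparison, where limma called 0, 0 and 1 gene. Each simulated gene varied independently, so this does not show how camera behaves where the members of a list vary together. In the real data the estimated correlation was 0.70 for interferon-stimulated genes and 0.10 for oxidative phosphorylation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and files were read with pandas 2.3.3, the data.table package (version 1.17.8) and jsonlite 2.0.0.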

Results

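Expression was measured in 12 corpora lutea, 4 from cows on day 15 of the estrous cycle (NP15), 4 from day 15 of gestation (P15) and 4 from day 18 of gestation (P18). The labels give a separate animal for each sample, so n = 4 animals per group, and this number of arrays limits the precision. The 75th percentile of the processed signal was 2868 to 4183 in NP15, 2649 to 3773 in P15 and 3000 to 3558 in P18. The share of probes well above background was 83.3% ± 2.59 (SD, n = 4) in NP15, 78.4% ± 2.44 in P15 and 70.4% ± 2.19 in P18. The negative controls' net signal was 34.7 to 38.5 in NP15, 32.1 to 36.5 in P15 and 78.8 to 92.2 in P18. NP15 and P15 shared slide 1 and scan 1, NP15 in slide row 1 and P15 in slide row 2. P18 lay alone on slide 2 and scan 2, in slide row 2. In both comparisons with NP15, slide row and group cannot be told apart. For both comparisons with P18, batch and group cannot be told apart. P18 vs NP15 also sets day 18 of gestation against day 15 of the cycle, so day and pregnancy cannot be told apart in it.

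Across genes, which are not independent replicates, the arrays correlated at 0.962 to 0.991 within NP15, 0.979 to 0.988 within P15 and 0.981 to 0.985 within P18. Between groups r was 0.957 to 0.990 for NP15 with P15, 0.944 to 0.974 for NP15 with P18 and 0.964 to 0.972 for P15 with P18. The first principal component held 34.5% of the variance and set the P18 arrays apart from the other 8. The second held 19.7% and set NP15 replicate 4, at -77.8, apart from the other arrays, which lay between -15.5 and 22.0. On the third, P15 replicate 4 was at -46.2 and the other arrays between -10.5 and 23.1. On NP15 replicate 4 4.08% of probes lay over 2 log2 units from the mean of the other NP15 arrays, against 0.317% to 1.29% on the other 11 arrays.

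The series asked how pregnancy changes PPARD and CYP21A2 in this gland. PPARD, a nuclear receptor for fatty acids, had a mean log2 value of -7.18 ± 0.62 (SD, n = 4) in NP15, -4.74 ± 0.07 in P15 and -3.47 ± 0.49 in P18 by its brightest probe, A_73_119402. It was 5.43-fold higher in P15 than in NP15 (log2 change 2.44, SE 0.30, limma adjusted p = 0.00229) and 13.1-fold higher in P18 (3.71, SE 0.30, adjusted p = 2.34e-05), with 4 of 4 arrays above all NP15 arrays each time. P18 was 2.42-fold above P15 (1.27, SE 0.30, adjusted p = 0.00935), again with all 4 arrays above. This probe lies in row 1 of the array, at its edge. The other PPARD probe, ABR1869 in row 141, changed by -0.53 (SE 0.30, adjusted p = 0.698) from NP15 to P15, so that call did not hold on it. The probes were not aligned to a transcript here, so which of them measures PPARD is not known. The other probe was well above background on 4 NP15 arrays, 2 P15 arrays and 0 P18 arrays, so its P18 value is not exact. A rise from NP15 to P18 as on the row 1 probe would have lifted it above background. Its mean was -6.65 in P18 and -6.74 in NP15, which goes against the P18 vs NP15 call if both probes measure PPARD. The call of P18 against P15 is not settled by it. With normexp, which adds an offset of 50 to each signal, PPARD on the row 1 probe was at 1.03 in P15 vs NP15 (adjusted p = 0.0253) and 1.97 in P18 vs NP15 (adjusted p = 5.22e-05). The mean of both probes gave a P15 change of 0.95 with an adjusted p of 0.157 and a P18 change of 1.91 (adjusted p = 0.000378); over the alternatives the P15 adjusted p ranged from 6.24e-05 to 0.932.

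CYP21A2, the adrenal 21-hydroxylase that turns progesterone into deoxycorticosterone, is measured by a probe in row 191, next to the opposite edge. Its mean log2 values were -1.81 ± 1.59 (SD, n = 4) in NP15, -3.78 ± 0.35 in P15 and -4.05 ± 0.89 in P18. P15 lay below NP15 on 4 of 4 arrays without passing the threshold (log2 change -1.97, SE 0.69, limma adjusted p = 0.360). NP15 replicate 3 was at 0.39, above the other NP15 arrays. Without it the change against NP15 was -1.24 in P15 and -1.51 in P18. In P18 it fell 4.73-fold against NP15 (-2.24, SE 0.69, adjusted p = 0.0307, 4 of 4 arrays), and P18 differed from P15 by -0.27 (adjusted p = 0.806). The P18 call was lost on the 8 arrays alone (adjusted p = 0.0725), after the local position adjustment (-1.33, adjusted p = 0.125) and with cyclic loess (-1.93, adjusted p = 0.0573), within a range of 0.0121 to 0.125 over the alternatives. It was also lost without NP15 replicate 1 (-2.20), P18 replicate 1 (-1.83) or P18 replicate 2 (-2.23), with adjusted p up to 0.0808. Without P18 replicate 1 the difference of P18 from P15 was 0.14, and after the local adjustment 0.13.

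**Figure D1:**
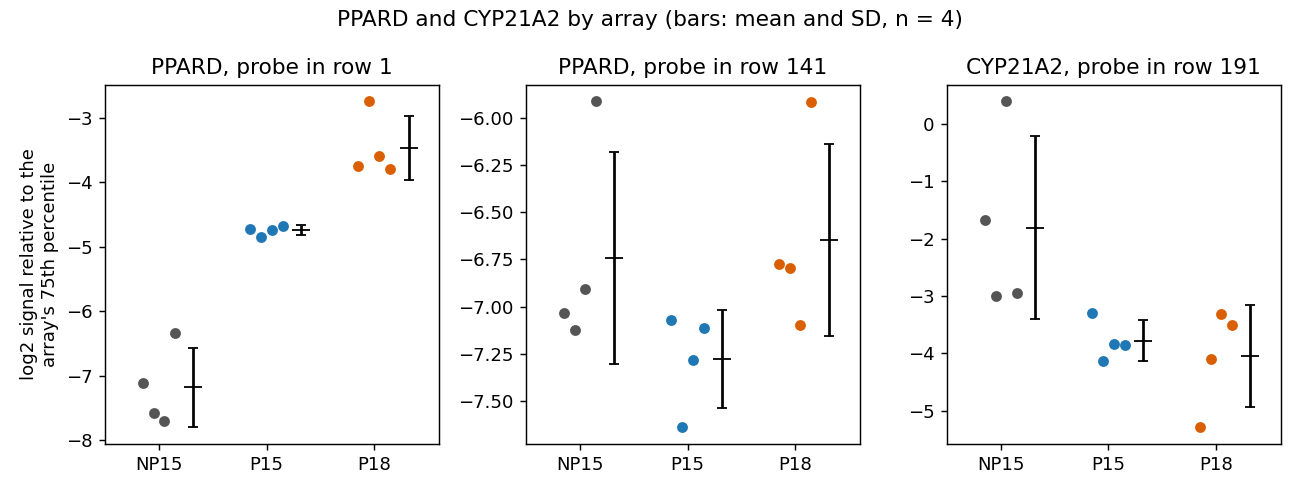
Log2 signal relative to each array's 75th percentile for the PPARD probes in rows 1 and 141 and the CYP21A2 probe in row 191, with a point per array and the mean ± SD of 4 arrays per group. The row 1 probe of PPARD rises from -7.18 to -4.74 and -3.47, while its row 141 probe lies between -7.64 and -5.91 on all 12 arrays and was not well above background on any P18 array.

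P15 and NP15 were cows of the same day that differed in pregnancy, with their arrays in different slide rows. Between them 124 of 12321 genes were called, 51 higher and 73 lower, of which 59 had a symbol. The homeobox gene MSX2 was 5.51-fold higher in P15 (log2 change 2.46, SE 0.14, limma adjusted p = 2.05e-05). LRRTM1, a synaptic adhesion protein, was 5.11-fold higher, PFN3, a profilin that binds actin, 4.17-fold, LAS1L, a ribosome assembly factor, 3.30-fold, MRPS28, a mitochondrial ribosomal protein, 3.26-fold, DLK1, a Notch-ligand homologue, 2.96-fold, and ITGB5, an integrin subunit, 2.90-fold (adjusted p from 7.36e-05 to 0.000872). HSD3B1, which converts pregnenolone to progesterone, fell 2.76-fold (-1.47, SE 0.16, adjusted p = 0.000872). LHX2, a LIM homeobox factor, fell 10.8-fold (-3.43, SE 0.52, adjusted p = 0.0132; 3 of 4 P15 arrays well above background).

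Several of the lower genes were not well above background on any P15 array. GLG1, a Golgi glycoprotein, was at least 1.48-fold lower (adjusted p = 0.0141), SOX9, a transcription factor, at least 1.36-fold (0.0227), ANGPTL7, an angiopoietin-like protein, at least 1.17-fold (0.000679) and the ribosomal protein RPL13 at least 1.04-fold (0.0147, 3 of 4 NP15 arrays measured). The zinc finger gene ZNF761 (adjusted p = 0.00305) and QPCT, an enzyme that forms pyroglutamate (0.0276), get no fold, each measured on 3 NP15 arrays. TG, thyroglobulin, fell with 1 P15 array measured, which leaves the size open (log2 change -2.14, SE 0.41, adjusted p = 0.0333). In each of the genes named as called here, the 4 P15 arrays lay wholly above or below the 4 NP15 arrays. With normexp background correction the calls of GLG1, ANGPTL7, ZNF761, RPL13, SOX9, TG and QPCT ended, and the changes were smaller, with TG at -0.52, LHX2 at -1.87 and LRRTM1 at 1.54. After the local position adjustment LHX2, GLG1, RPL13, SOX9, TG and QPCT no longer passed. On the 8 slide 1 arrays alone SOX9, TG and QPCT did not pass, nor did QPCT with quantile normalization or LHX2 with marked spots kept. Calls were also lost with 1 array left out: LHX2 without NP15 replicate 3 (adjusted p 0.0600), RPL13 without NP15 replicate 2 (0.0524), SOX9 without any 1 NP15 array or P15 replicate 1 (up to 0.0726), QPCT without any P15 array or NP15 replicate 1, 2 or 4 (up to 0.0858) and TG without any NP15 or P18 array or P15 replicate 2 (up to 0.114).

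Position on the array went with these calls. All 51 rises lay in the first 24 rows and 67 of the 73 falls in the last 24, so 118 calls (95.2%) were in rows that hold 24.8% of the genes tested. The median log2 change was 0.48 in row 1 and -0.72 in row 192, against -0.05 in the inner rows. MSX2, PFN3, MRPS28 and ITGB5 lie in row 1, LAS1L in row 2, LRRTM1 in row 3, DLK1 in row 7, and the named genes that fell lie in rows 190 to 192. Without these outer rows limma called 0 of 9293 genes, with 392 at an unadjusted p under 0.05, fewer than chance would give.

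**Figure D2:**
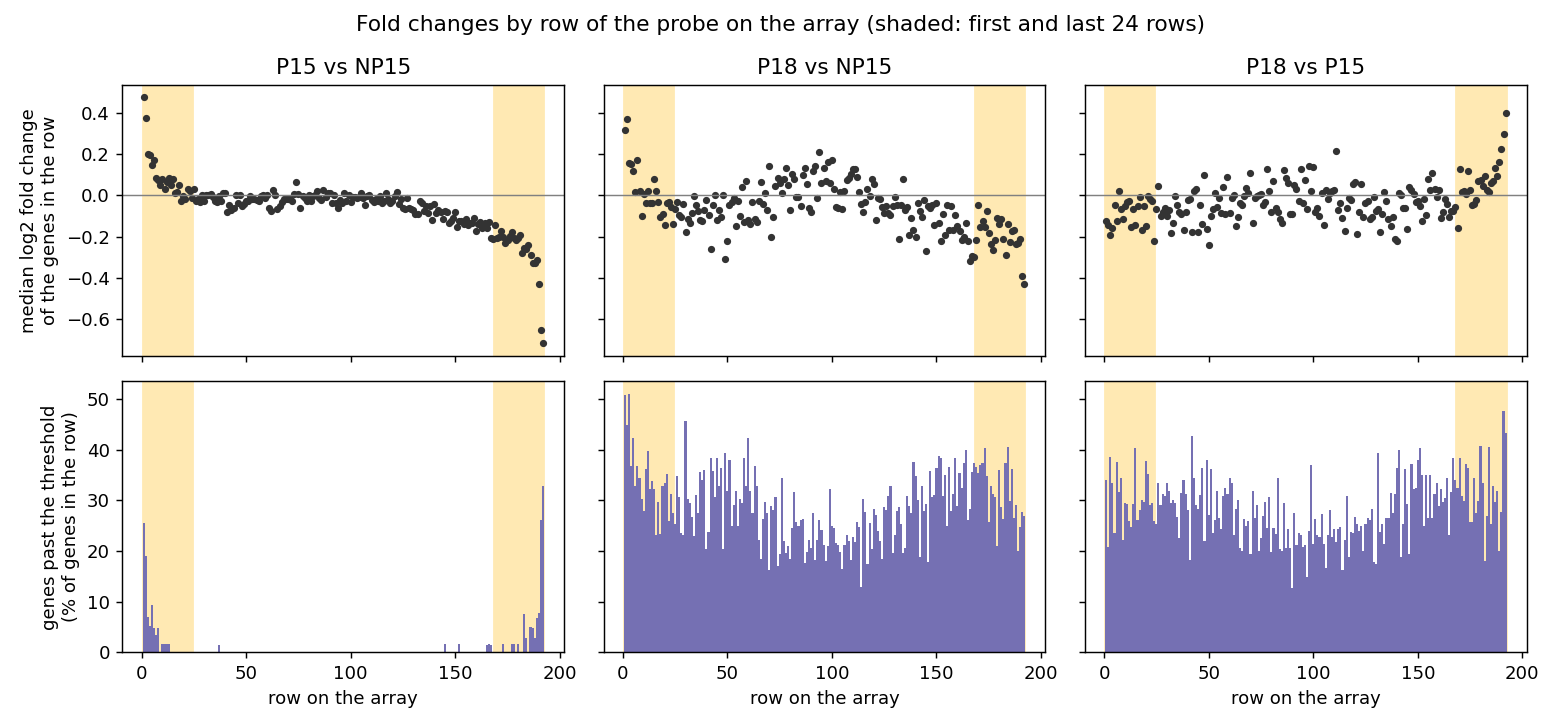
Median log2 change of the genes in each array row and percent of those genes past the threshold, by row from 1 to 192, for the 3 comparisons, with the first and last 24 rows shaded. For P15 vs NP15 the median runs from 0.48 in row 1 to -0.72 in row 192 and the calls gather in the shaded rows.

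At an unadjusted p under 0.05 there were 1080 genes, where 616 would come by chance and another split of the 8 arrays gave up to 981, and 76 called genes changed at least 2-fold. In all 124 called genes the groups did not overlap, which chance alone gives in 2.86% of unselected genes. Calling genes on the same arrays favours genes without overlap, so this adds no separate support. The count was 58 on the 8 slide 1 arrays alone, 124 with slide as a fixed block (the same by construction), 74 with normexp, 50 after the local position adjustment and 219 with array weights. It was 62 without NP15 replicate 1, 65 without NP15 replicate 2, 70 without NP15 replicate 3, 64 without P15 replicate 2 and 78 without P15 replicate 3, and without NP15 replicate 4, the array that stood apart, it was 97. Higher genes were 41.1% of the calls, 59.5% with normexp and 54.8% on probes above background on all 12 arrays.

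Of 25 lists, 2 were shifted in P15 by camera. The oxidative phosphorylation genes, subunits of the respiratory chain, were lower as a group (mean -0.11, 51 of 64 members lower, adjusted p = 0.00173), with the list's mean on the 4 P15 arrays below all NP15 arrays. With an estimated correlation the adjusted p was 0.618, and of its members 0 passed limma's test over all genes and 0 adjusted over the list alone. SDHD, of complex II, had a log2 change of -0.77 (SE 0.18, adjusted p = 0.0918), past the threshold without NP15 replicate 1 (-0.97), and the complex IV subunits COX5B -0.49 (adjusted p = 0.241) and COX7C 0.40 (0.108). All 3 lie in outer rows, and after the local position adjustment SDHD was at -0.22 (adjusted p = 0.944), COX5B at 0.01 and COX7C at -0.07; COX7C passed with array weights and with cyclic loess. The angiogenesis and vascular tone list was higher (mean 0.13, 20 of 31 members higher, adjusted p = 0.0247; adjusted p = 0.618 with an estimated correlation), with 1 member higher over all genes and 1 adjusted over the list alone.

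That member was ACE, which makes angiotensin II (0.77, SE 0.13, adjusted p = 0.0209, row 11, 4 of 4 arrays higher); AGTR1, a receptor for it, was at 0.48 (SE 0.17, adjusted p = 0.371). The ACE call was lost with normexp (0.55), on the 8 arrays alone, after the local adjustment (0.66, adjusted p = 0.132, the highest over the alternatives, whose lowest was 0.00668) and without NP15 replicate 1, 2 or 3 or P15 replicate 1, 3 or 4 (up to 0.0679). The list's shift was lost with no filter, with cyclic loess and without NP15 replicate 2 (mean 0.08), NP15 replicate 3 (0.11) or P15 replicate 4 (0.09). Lists shifted numbered 1 without NP15 replicate 2, NP15 replicate 3 or P15 replicate 4, and 4 without P15 replicate 1, P15 replicate 2 or P18 replicate 2.

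None of the other 23 lists passed, the closest being immediate early and heat shock genes (adjusted p = 0.0714, mean 0.21), where P15 replicate 4 was at 0.84 and the other P15 arrays between -0.32 and 0.07. In steroid and progesterone synthesis, 1 of 27 members rose and 1 fell, as also adjusted over the list alone. SCP2, a sterol carrier in row 4, rose by 0.93 (SE 0.19, adjusted p = 0.04998, 4 of 4 arrays), just within the threshold, and the faller was HSD3B1 in row 192, also the only member of the luteal cell list to pass. The SCP2 call was lost under 11 of the alternatives, among them quantile normalization, and without any array but P15 replicate 1 (adjusted p up to 0.158). FDXR, which passes electrons by way of ferredoxin to the side-chain cleavage enzyme, was at -0.55 (SE 0.17, limma adjusted p = 0.281). CYP11A1, that enzyme, was at -0.25 (SE 0.11, adjusted p = 0.533). In the PPAR list 1 of 29 members passed, PPARD, and in the ribosomal list 1 of 64, RPL13. Interferon-stimulated genes had 0 of 26 members past limma's threshold, with IFIT5 at 0.66 (SE 0.45, adjusted p = 0.770) and OAS1X at 1.31 (SE 1.09, adjusted p = 0.803). Adjusted over the list alone, 1 member of the T and natural killer cell list was higher and 1 lower, and 1 of the B cell list lower, none over all genes. The trophoblast list, with 2 members measured (mean -0.53), was not tested. In 11 lists, none of them shifted, the median differed in sign from the test, and in the endothelial list the mean (-0.03) differed from both.

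Between P18 and NP15, 3565 genes were called, 1276 higher and 2289 lower, of which 1568 had a symbol. KLC3, a kinesin light chain, was 11.1-fold higher in P18 (log2 change 3.47, SE 0.14, limma adjusted p = 5.68e-07). OAS1X, an antiviral enzyme induced by interferon, was 10.9-fold higher (3.45, SE 1.09, adjusted p = 0.0345) and ISG15, a ubiquitin-like protein induced by interferon, 6.52-fold (2.70, SE 0.93, adjusted p = 0.0494). SCARB1, the receptor that takes up cholesterol from high-density lipoprotein, fell 2.20-fold (-1.14, SE 0.12, adjusted p = 0.000102), and PTGFR, the receptor through which prostaglandin F2 alpha starts luteal regression, rose 2.56-fold (1.36, SE 0.24, adjusted p = 0.00177). For each gene named as called in this comparison the 4 P18 arrays lay wholly above or below the 4 NP15 arrays.

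Other large rises were in PENK, the enkephalin precursor (log2 change 3.03, limma adjusted p = 0.0230), and the tight junction protein CLDN18 (2.77, 5.22e-05). PENK was measured on 2 arrays of each group and CLDN18 on 3 P18 arrays and 1 NP15 array, which leaves both sizes open. BPIFA2B, a salivary-type secreted protein, rose 6.28-fold (0.000216, 4 and 3 measured) and the homeobox gene ALX4 at least 4.71-fold (1.44e-05, 3 P18 arrays measured). Most of the largest falls were in genes not well above background on any P18 array. These were IFNAR1, a chain of the type I interferon receptor (at least 1.84-fold, adjusted p = 4.13e-05), PTPRC, the leukocyte antigen CD45 (1.78-fold, 0.00481), the stress kinase MAPK9 (1.72-fold, 1.17e-05), the matrix protein MATN2 (1.59-fold, 9.38e-05), the phosphatase PGP (1.18-fold, 3.92e-05), ARHGEF25, a guanine nucleotide exchange factor (1.16-fold, 0.00312), and TMEM30C (1.06-fold, 1.42e-05), each value a lower bound. CSAD, an enzyme of taurine synthesis, fell 5.31-fold (-2.41, SE 0.14, adjusted p = 6.17e-06) with 2 P18 arrays measured. Normexp gave smaller changes for these genes: CLDN18 was at 1.00, PENK at 1.66, BPIFA2B at 1.15, ALX4 at 1.06 and CSAD at -1.34, all still called. Of the 2289 lower genes, 482 were not well above background on any P18 array. The same held for 54 of the 1276 higher genes, which leaves the size of those rises open.

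The oxidative phosphorylation genes were higher in P18 (mean 0.24, 49 of 64 members, adjusted p = 3.01e-06; adjusted p = 0.745 with an estimated correlation), with the list's mean on the 4 P18 arrays above all NP15 arrays. Over all genes 22 members rose and 0 fell, and the same numbers held adjusted over the list alone. Examples were NDUFB2 (0.97, SE 0.09, adjusted p = 4.71e-05) and NDUFC1 (0.74, SE 0.10) of complex I, UQCRFS1 (0.67, SE 0.10) of complex III and COX7A2 (0.81, SE 0.12, adjusted p = 0.000559) of complex IV. The extracellular matrix and protease list was lower (mean -0.55, 23 of 31 members, adjusted p = 0.0326; adjusted p = 0.745 with an estimated correlation), on 4 of 4 arrays. Its members gave 0 rises and 13 falls over all genes and 1 rise and 14 falls adjusted over the list alone. They include COL18A1 and COL4A1 of basement membranes (-1.68, SE 0.16, and -1.19, SE 0.16), COL1A2 of fibrillar collagen (-1.35, SE 0.26, adjusted p = 0.00284) and the procollagen protease ADAMTS2, at least 1.00-fold lower (adjusted p = 3.92e-05).

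The shift of the matrix list was lost with quantile normalization, without the outer rows, and without NP15 replicate 1 (mean -0.52) or P18 replicate 3 (-0.53). The interferon-stimulated genes were higher (mean 0.69, 22 of 26 members, camera adjusted p = 0.0386, and 0.858 with an estimated correlation). Of the members 2 were past limma's threshold over all genes and 0 adjusted over the list alone. Among all 12321 genes 1276 rose, so 2 of 26 was not a larger share. On P18 replicate 3 the list's mean was 1.67, against -0.11 to 0.08 on the other 3 P18 arrays, and without that array the mean was 0.27 (adjusted p = 0.387). It was also lost without NP15 replicate 1 (mean 0.61) or NP15 replicate 2 (0.65), with quantile normalization, median centring, normexp, cyclic loess or no filter, and without the outer rows. MX1, an antiviral GTPase, was at 1.92 (SE 0.68, adjusted p = 0.0539, 0.0335 to 0.0741 over the alternatives) and DHX58, an RNA sensor, at 1.33 (SE 0.49, adjusted p = 0.0606, 0.0334 to 0.0800 over the alternatives), all 4 P18 arrays above NP15 for both. MX1 passed under 6 of the alternatives, median centring and normexp among them, and DHX58 under 5. MX1 also passed without P15 replicate 1, P15 replicate 4 or P18 replicate 4 (2.29) and DHX58 without P18 replicate 4 (1.62).

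Without P18 replicate 3 the log2 change of OAS1X was 2.62 and that of ISG15 1.99. The ISG15 call was lost with quantile normalization, cyclic loess, without the outer rows and without any 1 array but NP15 replicate 4, P15 replicate 2 and P15 replicate 4 (adjusted p up to 0.130). That of OAS1X was lost with array weights and without NP15 replicate 1, 3 or 4 or P18 replicate 3 or 4 (up to 0.0926), and that of PENK without NP15 replicate 1 or 3 or P18 replicate 1 or 4 (up to 0.0647). Lists shifted numbered 1 without NP15 replicate 1 or P18 replicate 3, and 5 without NP15 replicate 3, NP15 replicate 4, P18 replicate 1 or P18 replicate 2.

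**Figure D3:**
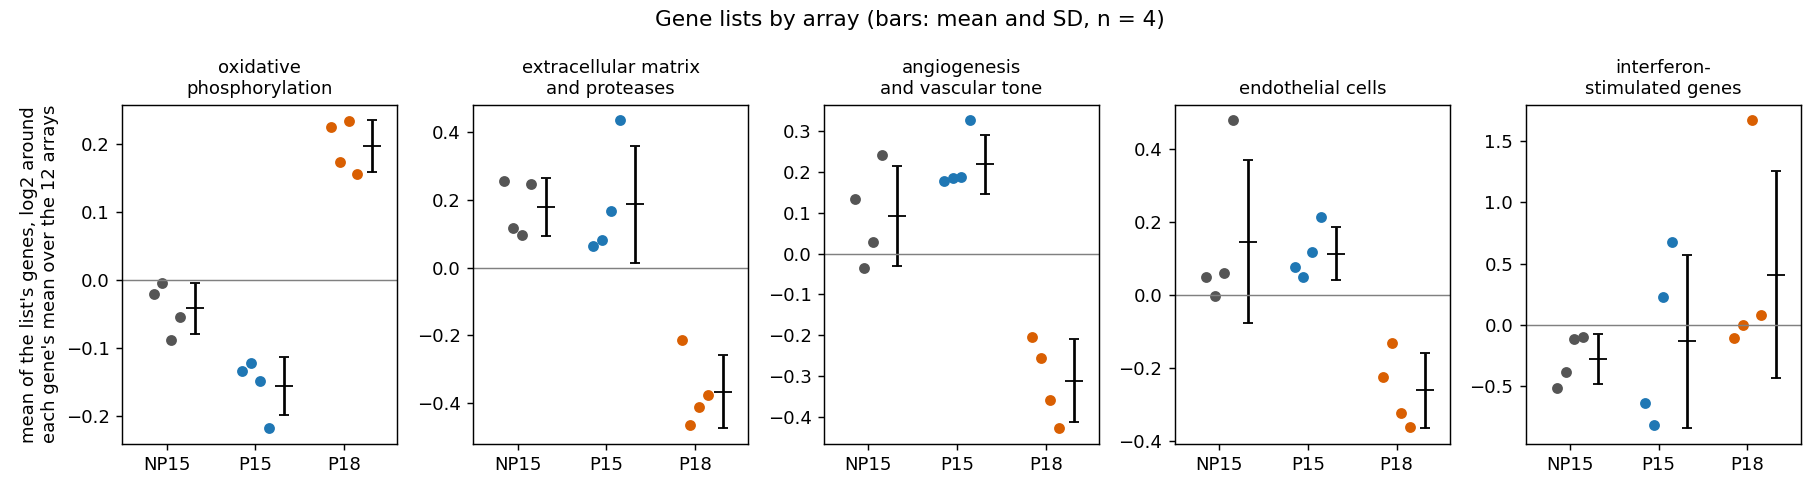
Mean log2 deviation of the members of 5 lists on each array from their mean over the 12 arrays, with a point per array and the mean ± SD of 4 arrays per group. Oxidative phosphorylation is at -0.04, -0.16 and 0.20 in NP15, P15 and P18, and the interferon-stimulated genes on P18 replicate 3 lie at 1.67, apart from the other 3 P18 arrays.

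The other lists did not pass in P18 vs NP15. Their counts of rises and falls stand beside 1276 and 2289 among all 12321 genes. In steroid and progesterone synthesis 2 of 27 members rose and 5 fell, likewise adjusted over the list alone. SCP2 rose by 1.08 (SE 0.19, adjusted p = 0.00200), and HSD3B1 (-0.70, SE 0.16, adjusted p = 0.00727) and PGRMC2, a membrane progesterone binding protein (-0.96, SE 0.16), fell. HSD3B1 lies in row 192, where the median change of all genes was -0.43, and its own change was -0.31 with quantile normalization and -0.46 with median centring, still called. Of the luteal cell markers 1 rose, PTGFR, and 3 of 10 fell (1 and 4 adjusted over the list alone). In cholesterol synthesis and uptake 1 of 20 members rose and 2 fell, SCARB1 among them. In the prostaglandin list 2 of 22 members rose and 5 fell, with PTGS2, the inducible cyclooxygenase, at least 2.10-fold lower (adjusted p = 0.00642) and PLA2G4A, which releases arachidonic acid, at least 1.36-fold lower (0.000946), both not well above background on any P18 array. Normexp ended the calls of PTGS2, PLA2G4A and PTPRC.

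Angiogenesis had 1 rise and 9 falls in 31 members (mean -0.40, adjusted p = 0.0862), endothelial markers 0 and 5 in 13 (-0.41, 0.0617), fibroblasts 0 and 4 in 12 (-0.58, 0.0862) and macrophages 3 and 0 in 14 (0.51, 0.0617; 5 and 1 adjusted over the list alone). Rises and falls were 3 and 4 of 29 in the PPAR list, 1 and 0 of 32 chemokines, 0 and 0 of 7 lymphatic genes, 1 and 4 of 23 in apoptosis, 5 and 8 of 64 ribosomal proteins, 0 and 2 of 22 immediate early genes, 2 and 7 of 21 in hypoxia and glycolysis and 0 and 3 of 21 cell cycle genes. They were 7 and 3 of 25 in complement, 2 and 0 of 18 in antigen presentation, 2 and 0 of 16 T and natural killer cell markers, 0 and 0 of 5 B cell markers, 1 and 0 of 6 red cell markers and 0 and 2 of 16 follicle genes. Adjusted over the list alone, rises and falls were 8 and 5 in complement, 5 and 7 in ribosomal proteins, 1 and 5 in endothelial markers, 0 and 2 in cell cycle, 0 and 1 in immediate early and in follicle genes, 1 and 0 in antigen presentation, 0 and 0 in T and natural killer cell markers, and the same as over all genes in the rest. The 2 trophoblast genes had a mean of 0.15.

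In P18 vs NP15, 4963 genes had an unadjusted p under 0.05 (616 by chance, up to 1944 in another split). Of the called genes 1250 changed at least 2-fold. In 3108 called genes the groups did not overlap (2.86% by chance in unselected genes), which calling them on the same arrays favours. The outer rows held 1002 of the calls (28.1%), and 2496 of 9293 genes were called without them. The direction of the calls went with position: rises and falls were 25 and 5 in row 1 and 2 and 16 in row 192. They were 269 and 241 in the first outer rows, 902 and 1661 in the inner rows and 105 and 387 in the last outer rows. Without NP15 replicate 4 there were 3936 calls, and 5373 with no filter. Higher genes made up 35.8% of the calls, 67.6% with median centring, which took the median change of all genes from -0.06 to 0.18, 55.7% with normexp and 56.1% with no filter, so the balance of rises and falls rests on these settings.

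Between P18 and P15, days 18 and 15 of gestation, 3486 genes were called, 1579 higher and 1907 lower, of which 1539 had a symbol. KLC3 was 12.3-fold higher in P18 (log2 change 3.62, SE 0.14, limma adjusted p = 3.55e-07). HIF1A, the oxygen-regulated transcription factor, fell 3.08-fold (-1.62, SE 0.12, adjusted p = 2.06e-05), SCARB1 fell (log2 change -1.38, SE 0.12, adjusted p = 4.10e-05) and HSD3B1 rose 1.71-fold (0.77, SE 0.16, adjusted p = 0.00429). The median change in row 192, where HSD3B1 lies, was 0.40, and after the local position adjustment its rise was 0.43 (adjusted p = 0.0374). PLCG1, a phospholipase of growth factor signalling, fell 4.50-fold (-2.17, SE 0.19, adjusted p = 3.69e-05; -1.30 with normexp). Each gene named as called here had its 4 P18 arrays wholly above or below the 4 P15 arrays.

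Rises of genes not well above background on any P15 array were at least 3.84-fold in BPIFA2B (adjusted p = 5.57e-05), at least 2.96-fold in CLDN18 (3.63e-05, 3 P18 arrays measured), at least 2.84-fold in PROC, the anticoagulant protein C (0.000268, 3 measured), and at least 2.79-fold in CELA3B, a pancreatic elastase (0.000384). FABP2, an intestinal fatty acid binding protein, rose 7.85-fold (2.97, SE 0.94, adjusted p = 0.0351, 3 P15 arrays measured), a call lost without P15 replicate 1 or 4 or P18 replicate 2, 3 or 4 (up to 0.0922), with a log2 change of 2.16 without P15 replicate 1. Falls with no P18 array well above background were at least 1.76-fold in MAPK9 (1.40e-05), 1.30-fold in RASAL2, an inhibitor of Ras (0.000623), 1.28-fold in RSPO3, an activator of Wnt signalling (0.00438), 1.18-fold in IL17RE, an interleukin 17 receptor (0.000150), 1.05-fold in PIK3R3, a subunit of phosphoinositide 3-kinase (0.00104), and 1.04-fold in MATN2 (0.000398). SERPINB2, a plasminogen activator inhibitor, also fell (adjusted p = 0.00931) and gets no fold. With normexp the calls of MATN2, RASAL2 and PIK3R3 ended, and BPIFA2B was at 1.21, CLDN18 at 1.00, PROC at 0.98, CELA3B at 0.92 and FABP2 at 1.60. Of the 1907 lower genes, 390 were not well above background on any P18 array. The same held for 133 of the 1579 higher genes, which leaves the size of those rises open.

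By camera, 4 lists were shifted. Oxidative phosphorylation genes were higher in P18 (mean 0.35, 60 of 64 members, adjusted p = 3.61e-11; adjusted p = 0.214 with an estimated correlation), with 29 rises and 0 falls over all genes and 31 rises adjusted over the list alone. Its members included NDUFB2 (0.96, SE 0.09), NDUFB3 (0.83, SE 0.10), UQCRFS1 (0.92, SE 0.10) and COX7A2 (0.87, SE 0.12, adjusted p = 0.000399). Angiogenesis and vascular tone was lower (mean -0.53, 27 of 31 members, adjusted p = 0.00299; adjusted p = 0.272 with an estimated correlation), with 0 rises and 7 falls by either adjustment. With HIF1A these were FGFR1, a fibroblast growth factor receptor (at least 2.29-fold lower), its ligand FGF1 (-0.91, SE 0.19), PDGFB, a growth factor that recruits pericytes (-1.25, SE 0.19, 3 P18 arrays measured, and -0.45 with normexp), and 3 others. The bound for FGFR1 holds for the main setting, and over the alternatives its log2 change was as small as -0.65. The extracellular matrix list was lower (mean -0.55, 24 of 31 members, adjusted p = 0.00317; adjusted p = 0.301 with an estimated correlation), with 1 rise and 14 falls (2 and 15 adjusted over the list alone). Fallers were COL18A1 (-1.82, SE 0.16), COL4A1 (-1.04, SE 0.16), FN1, fibronectin (-1.86, SE 0.34), and ADAMTS2, which gets no fold.

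Endothelial markers were lower as a group (mean -0.37, 12 of 13 members, adjusted p = 0.0195; adjusted p = 0.652 with an estimated correlation), with 1 rise and 5 falls by either adjustment. CDH5, the endothelial cadherin, fell by 1.21 (SE 0.14), PECAM1, a junction protein, by 1.06 (SE 0.15) and ERG, an endothelial transcription factor, by 1.36 (SE 0.24). PLVAP, a protein of capillary fenestrae, rose by 1.96 (SE 0.42, adjusted p = 0.00573), with 2 P18 arrays and 1 P15 array measured, which leaves the size open. With normexp PLVAP was at 0.91, PECAM1 at -0.68 and ERG at -0.86. For all 4 lists the mean on each P18 array lay on that side of all 4 P15 arrays. Lists shifted numbered 7 without P15 replicate 4 and 8 without P18 replicate 1. Over the 3 comparisons 0 list shifts held with an estimated correlation, while limma's fry, which tests whether a list moves one way on balance, called 0, 11 and 8 lists in the order described. The median differed in sign from the test in 4 lists for P18 vs NP15 and 2 for P18 vs P15, none of them shifted, as did the means of the cholesterol and immediate early lists for P18 vs NP15.

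**Figure D4:**
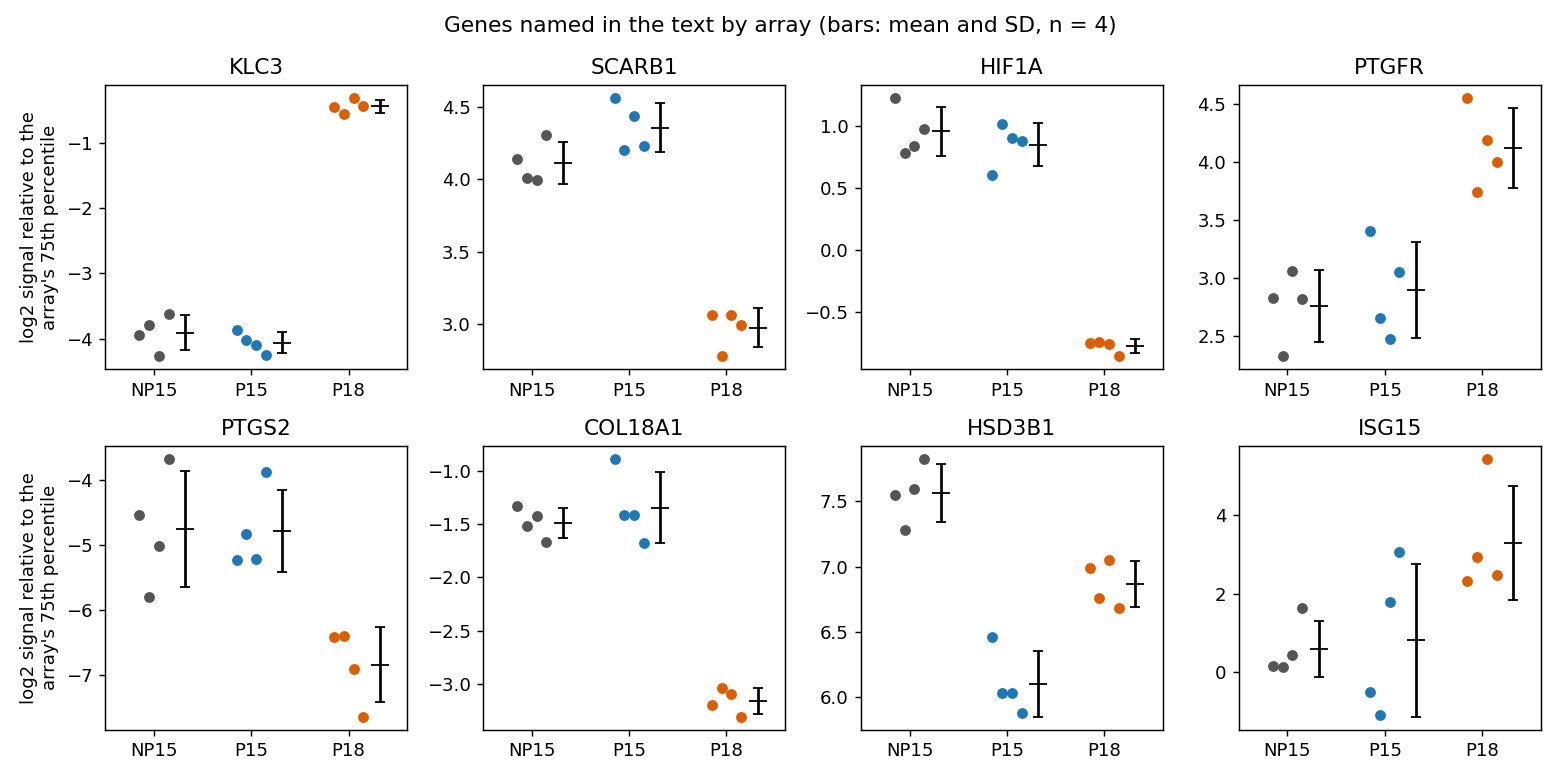
Log2 signal relative to each array's 75th percentile for KLC3, SCARB1, HIF1A, PTGFR, PTGS2, COL18A1, HSD3B1 and ISG15, with a point per array and the mean ± SD of 4 arrays per group. KLC3 is at -3.91, -4.06 and -0.44 in NP15, P15 and P18, and PTGS2 was not well above background on any P18 array.

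None of the remaining lists passed between P18 and P15. Among all 12321 genes 1579 rose and 1907 fell. Rises and falls over all genes were 0 and 1 of 26 interferon-stimulated genes (mean 0.54, adjusted p = 0.133, with P18 replicate 3 again at 1.67 against -0.11 to 0.08), 2 and 2 of 27 in steroid synthesis, 4 and 1 of 20 in cholesterol synthesis and uptake (5 and 1 adjusted over the list alone), 3 and 2 of 29 in the PPAR list, 2 and 4 of 22 in the prostaglandin list, 1 and 1 of 32 chemokines and 0 and 0 of 7 lymphatic genes (mean 0.79). They were 1 and 3 of 23 in apoptosis, 5 and 6 of 64 ribosomal proteins, 0 and 2 of 22 immediate early genes, 1 and 5 of 21 in hypoxia and glycolysis, 1 and 2 of 21 cell cycle genes, 3 and 3 of 25 in complement and 2 and 0 of 18 in antigen presentation. Among cell types they were 2 and 2 of 10 luteal markers, 0 and 4 of 12 fibroblast markers (mean -0.55, adjusted p = 0.0711), 3 and 0 of 14 macrophage markers (mean 0.52, adjusted p = 0.0936), 0 and 0 of 16 T and natural killer cell markers, 1 and 0 of 5 B cell markers, 2 and 0 of 6 red cell markers (4 and 0 adjusted over the list alone) and 0 and 2 of 16 follicle genes. Adjusted over the list alone, rises and falls were 0 and 0 in interferon-stimulated genes, 1 and 0 in chemokines and in antigen presentation, 1 and 2 in apoptosis, 0 and 1 in cell cycle and in follicle genes, and otherwise the same. The 2 trophoblast genes had a mean of 0.67.

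In P18 vs P15, 4861 genes had an unadjusted p under 0.05 (616 by chance, up to 1596 in another split). Of the called genes 1168 changed at least 2-fold and 88 were not well above background in either group. In 3135 called genes the groups did not overlap (2.86% by chance in unselected genes), which calling them on the same arrays favours. The outer rows held 953 of the calls (27.3%), and 2509 of 9293 genes were called without them. Here too direction went with position: rises and falls were 5 and 15 in row 1 and 26 and 3 in row 192. They were 157 and 295 in the first outer rows, 1122 and 1411 in the inner rows and 300 and 201 in the last outer rows. Without NP15 replicate 4 there were 4330 calls, and 5298 with no filter. Higher genes made up 45.3% of the calls, 72.9% with median centring, which took the median change of all genes from -0.03 to 0.20, 60.5% with normexp, 62.8% with no filter and 31.5% after the local position adjustment.

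The comparisons of P15 and of P18 with NP15 share the NP15 arrays. Across 12321 genes their log2 changes correlated at r = 0.300, with a covariance of 0.0740, against r = 0.503 and a covariance of 0.0534 in 20 simulations of unchanged groups. The simulations gave all groups the same spread, while the sharing acts through NP15 alone. NP15 replicate 4 differed from the other NP15 arrays with an SD of 0.878 to 0.917, against 0.444 to 0.473 among those. The simulated covariances, here and in the inner rows, may be too low, so an excess over them shows no common change. With the NP15 arrays split so that each comparison had its own 2, r was 0.00154 to 0.0834 and the covariance averaged 0.0108 over 6 splits. Among genes called in both, 38 were higher in both (5.28 if independent), 24 lower in both (13.6) and 7 lower in P15 and higher in P18, and 65 of these lay in the outer rows. The numbers under independence ignore the shared NP15 arrays, which can raise these counts without any common change. In the inner rows the covariance was 0.0595 against 0.0554 simulated, and averaged -0.0119 with split NP15 arrays, with 0 genes higher and 2 lower in both by limma.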

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

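The tests chosen only after the results were seen were those of a local defect on NP15 replicate 4 and of a shift of 1 size on neighbouring spots, and the alternatives without the outer rows, with the local position adjustment, with cyclic loess and with the other probe of PPARD.

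The P15 vs NP15 calls gathered in the outer rows of the array. The software's detrending cannot be the whole of it, since 74 of 74 calls on signals before detrending lay there. Nor can a shift of 1 size on neighbouring spots, since 96% of the 50 calls after the local position adjustment still did. At the edge, neighbouring rows lie only inward, where the change was smaller (median 0.48, 0.38 and 0.20 in rows 1, 2 and 3). A shift that grows towards the edge is therefore not excluded. For the 3 called genes with a second probe, COX17, H3-3A and PPARD, that probe gave a median ratio to the called probe of -0.119 and 0 of 3 in the same direction, which argues against a change of the gene only if both probes measure it, and they were not aligned to a transcript. Relative to their inner copies, control spots were 0.41 higher in P15 in the first 24 rows and lower in the last (-0.35). Both differences were past the limits set beforehand for a signal change shared by all spots there (exact permutation p = 0.0286 each). But only 8.98% and 7.87% of their spots were above the lowest signal well above background, so such a change stays open. A change with pregnancy alone has no reason to sort rises and falls by array row. The first 24 rows held 51 rises and 0 falls, the inner rows 0 and 6, and the last 24 rows 0 and 67. These values argue against it as the cause of the calls as a set. For single genes that have no second probe it stays open. As each group filled its own row of the slide, slide row and group cannot be told apart.

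NP15 replicate 4 stood apart, with 4.08% of its probes over 2 log2 units from the other NP15 arrays, 456 of 514 of them lower. In the block of rows 109 to 120 and columns 31 to 40 the share was 73.0%, 17.9 times that of the whole array, and 8 of 131 blocks, with 5.33% of the probes, held 64.2% of the deviating ones. A local defect on that array's surface may account for these. The ratio alone is not specific, since it was 11.7 to 17.5 on the other NP15 arrays, whose reference mean includes this one, but their highest block share was 6.67%. A difference of that animal was not tested and stays open for the probes outside those blocks.

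P18 differed from both other groups in many genes and lay alone on its slide. Across the 182 genes with 2 probes the P18 vs P15 changes of both correlated at r = 0.285 (0.372 over 102 genes with both in inner rows), between the 0.2 set for an effect that differs from spot to spot and the 0.5 set against it. The spike-in controls, whose RNA is meant to be the same on all arrays, differed by a mean of 1.03 and an SD of 0.633 log2 between P18 and P15. Between P15 and NP15, on the same slide, these were 0.17 and 0.31. But only 7.58% of their spots were above the lowest signal well above background, so they do not measure the slide. An effect of slide or scan and a change from day 15 to day 18 therefore cannot be told apart, and either may contribute.

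Other splits of the 8 arrays of a comparison into 4 and 4 were counted. For P15 vs NP15 1 of 35 splits, the real one, gave as many genes, with 124 against at most 1 in the others. For P18 vs NP15 it was 1 of 35, with 3565 against at most 7, and for P18 vs P15 1 of 35, with 3486 against at most 1. With 35 splits no share under 1 of 35 is possible, and each other split mixes the groups, which widens the spread within its arms. The counts make a grouping by chance unlikely without excluding it, and bear on neither slide nor array position.

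Of 319 groups of 4 arrays, 24 held an array far from the other 3, where 16 would come by chance at about 1 in 20. Of these, 6 were on NP15 replicate 4, 6 on P15 replicate 4, 3 on P18 replicate 4 and at most 2 on any other array. As the difference from the mean of the group's other 3 arrays, NP15 replicate 4 stood apart in COX7A2 (0.24), FN1 (-1.57), IFIT5 (-1.69), PIK3R3 (-1.33) and the endothelial list (0.44), besides its share of deviating probes. On P18 replicate 3 these were IFIT5 (1.58) and the interferon-stimulated list (1.68). Among single genes they were also ARHGEF25 on NP15 replicate 3 (-1.96), SDHD on NP15 replicate 1 (-0.80), LHX2 (0.51) and NDUFB3 (0.16) on P15 replicate 1, COX5B (-0.44), NDUFC1 (-0.20) and PFN3 (-0.55) on P15 replicate 4, GLG1 on P18 replicate 2 (-2.30), and HIF1A (-0.11) and RASAL2 (1.24) on P18 replicate 4. Among lists they were steroid synthesis on P15 replicate 2 (0.125), angiogenesis (0.14), lymphatic vessels (-1.34) and fibroblasts (0.33) on P15 replicate 4, immediate early genes on P18 replicate 2 (0.67) and cell cycle on P18 replicate 4 (1.29).

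The changes of P15 and of P18 against NP15 differed by the direct test of P18 against P15 in 3486 genes, with day and slide not told apart. They also differed in PPARD (1.27) and in the means of oxidative phosphorylation (0.35), angiogenesis (-0.53), extracellular matrix (-0.55) and endothelial markers (-0.37). With an estimated correlation these 4 list differences did not pass by camera (adjusted p = 0.214, 0.272, 0.301 and 0.652). That of PPARD rests on its row 1 probe. On the other probe, not well above background on any P18 array, it was not called (limma adjusted p = 0.144).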

How the results depend on the processing

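The alternatives chosen only after the results were seen were those without the outer rows, the local position adjustment, cyclic loess and the other probe of PPARD. Dim probes limit the data: the 70.4% of probes well above background in P18 leave many falls as bounds. Except where the setting itself uses fewer genes or arrays, the cause of a change was not tested.

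P15 vs NP15 gave 74 genes with normexp, 219 with array weights, 58 on the 8 arrays and 50 after the local adjustment. By limma without the outer rows it gave 0, with 392 at an unadjusted p under 0.05, fewer than chance would give. No filter gave 5373 genes for P18 vs NP15 and 5298 for P18 vs P15; their other settings stayed within 1.5 times the first count. With 1 array left out the counts were 62 to 115, 2843 to 3936 and 2822 to 4330 in the 3 comparisons. For P15 vs NP15, 62 came without NP15 replicate 1, 65 without NP15 replicate 2, 70 without NP15 replicate 3, 64 without P15 replicate 2 and 78 without P15 replicate 3.

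PPARD was at -0.53, 0.10 and 0.63 in the 3 comparisons both without the outer rows and by its other probe. That probe was not well above background on any P18 array, so 0.10 and 0.63 are not exact. A rise of 3.71 in P18 vs NP15, as on the row 1 probe, would have shown on it. By the mean of its probes PPARD was at 0.95 in P15 vs NP15. CYP21A2 in P18 vs NP15 lost its call on the 8 arrays (-2.24), after the local adjustment (-1.33) and with cyclic loess (-1.93). In P18 vs P15 it turned to 0.13 after the local adjustment and to 0.14 without P18 replicate 1. With 1 array left out it ranged from -2.64 to -1.51 in P18 vs NP15, without a call when NP15 replicate 1 (-2.20), P18 replicate 1 (-1.83) or P18 replicate 2 (-2.23) was missing, and from -0.52 to 0.14 in P18 vs P15. COX5B and COX7C turned to 0.0074 and -0.0747 in P15 vs NP15 after the local adjustment, neither having passed.

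Lists shifted in P15 vs NP15, 2 at first, were 1 with no filter or cyclic loess and 4 on the 8 arrays. In P18 vs NP15, 3 at first, they were 1 with quantile normalization, 5 with normexp, array weights or the 8 arrays, 6 with no filter and 7 on probes above background on all 12 arrays. With 1 array left out they were 1 to 4, 1 to 5 and, from 4, 4 to 8. The lowest came without NP15 replicates 2 and 3 and P15 replicate 4, then without NP15 replicate 1 and P18 replicate 3. The highest came without P15 replicates 1 and 2 and P18 replicate 2, then without NP15 replicates 3 and 4 and P18 replicates 1 and 2, then without P18 replicate 1 (7 without P15 replicate 4).

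The shared replicate numbers, which are also slide columns, were not taken as pairs, since not all 4 pairs passed r = 0.1. Same-numbered arrays deviated together at r of 0.0975 to 0.294 (P15 and NP15), -0.0436 to 0.173 (P18 and NP15) and -0.0282 to 0.148 (P18 and P15), over 0.1 in 3, 1 and 1 of 4 pairs, and 3, 2 and 2 of 4 correlated best with their own number. With a replicate block the counts were 71, 3503 and 3444 genes and 2, 5 and 5 lists. In P15 vs NP15 the genes ACE, GLG1, RPL13, SCP2, SOX9 and TG were not called with that block.

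For the 96 gene results named in the text, 1230 values under the alternatives kept direction and side of the threshold, 47 lost the threshold, 13 gained it and 2 turned. With 1 array left out these numbers were 1012, 63, 5 and 0. For the shifted lists 127 kept it and 10 lost it, and 100 and 8 with 1 array left out.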

Other observations

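Some genes are measured by a second probe elsewhere on the array. Of the called genes with 2 kept probes, 24 of 37 in P18 vs NP15 and 24 of 34 in P18 vs P15 moved the same way on the second probe, and for 13 and 8 that probe was itself past the threshold in that direction, for 3 and 3 in the opposite one. COX17, a copper chaperone of complex IV, and the histone gene H3-3A were chosen after their values were seen. In P18 vs NP15 they were higher on the called probes (1.03 and 0.87) and on the second probes (1.12 and 0.52, limma adjusted p = 0.000158 and 0.0432).

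The probe of CYP21A2 lies in column 5 of row 191, within the block of rows 181 to 192 and columns 1 to 10, where 32.9% of probes on P18 replicate 1, 14.1% on P18 replicate 4 and 9.41% on P18 replicate 2 were over 2 log2 units from the other P18 arrays. No P18 array had a saturated probe, against 3 to 7 on NP15 arrays and 2 to 6 on P15 arrays.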
